A study of Mus musculus with 8 samples.

How the data were processed

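Total RNA from frozen brain (a section through the whole organ, per the labels' protocols) of 8 adult mice was measured, 4 homozygous for a mutated Pus1 gene and 4 wild type. The mice were 14 to 16 weeks old and had a C57BL/6J background after 5 generations of backcrossing. From each mouse 200 ng of RNA was labelled with either Cy3 or Cy5. Each of the 4 arrays, all on 1 slide, held 1 mutant and 1 wild-type mouse of the same sex and number, called a pair here. Pairs 1 and 2 were female and pairs 3 and 4 male. The mutant was in Cy5 in pairs 1 and 3 and in Cy3 in pairs 2 and 4, so each sex held both dye orientations. The arrays shared 1 slide and 1 scan setting, so these gave no batch to separate. Pairs 1 and 3 differed as a set from pairs 2 and 4, a division that coincides with dye orientation. In the mutant over wild-type ratios, dye can therefore not be told apart from another difference between these sets. In the levels of the single mice, both sets held both dyes, so a dye bias common to the arrays cannot give the difference. Both sets held both genotypes, and the median of the ATF4 target list averaged 0.614 over pairs 1 and 3 and 0.554 over pairs 2 and 4.

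The arrays were Agilent 2-colour gene expression arrays scanned and quantified with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The intensity values used were the median pixel brightness of each spot and of its local background in each channel, with no correction, per the file headers. The processed intensity of each channel had been background-subtracted and dye-normalized by linear and lowess steps within the array, per the file headers. The deposited log10 ratio is that of processed Cy5 over processed Cy3. The deposited spot marks (other values, 0 or 1) say whether a spot was well above background, saturated or an outlier, per the file headers. A mean spot intensity had been planned; the columns used here hold the median, which took its place.

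The authors also deposited a table of log2 values for the 8 samples, with no statement of its scale in the sources used here. It was set against the scanner values for the brighter probes that occurred once on the array, and dim probes were not compared. Each column followed the log2 processed signal after quantile normalization over the 8 channels, minus each probe's median over the samples, with r above 0.999. Its column medians in wild type were -0.0496, 0.0364, -0.00529 and 0.0345 for pairs 1 to 4, and in the mutant -0.0271, 0.0199, -0.0142 and -0.00238. Scale, centring and direction were settled by that comparison for the probes it covered, and the table was used as an alternative. It was matched to the arrays by probe name.

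Each array held 62976 spots, of which 3671 were controls, and 55681 different probes. Spot medians were corrected with normexp (offset 50, which draws the ratios of dim spots toward 0) on all spots, and log2 ratios were normalized within each array by loess with control spots at weight 0. Spots marked as outliers were left out, saturated spots were kept, and spots of 1 probe were averaged. Levels per channel were taken after Aquantile normalization between arrays. A probe was tested if it was well above background in at least 3 of the 4 samples of either genotype. This held for 33308 probes. Of these, 8 had an outlier spot that left an array without a value, and the other 33300 were tested. Probes were named by their accession, without version, through a RefSeq gene table of assembly GRCm38.p6, which gave a symbol to 27509 probes and none to 28172. The headers name an older build, so no coordinates are given and the table served only for names, chromosomes and gene order. Of the tested probes 20037 had a symbol, for 15283 genes. A gene is represented by its brightest tested probe.

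The ratios were fitted in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) with genotype coded by dye orientation and a dye term for each probe, which left 2 residual degrees of freedom and 3.65 from the prior. The within-array ratio makes the pair a block. The spread in this fit comes only from the difference between pairs of the same orientation, pair 1 against 3 and pair 2 against 4. A shift shared by pairs 2 and 4 is taken up as dye, so a gene can pass with pairs far apart. No probe had a dye effect at adjusted p under 0.05 in limma. A fit of dye orientation alone had 4167 probes at an unadjusted p under 0.05, where 1665 would be expected by chance. A dye effect is therefore not excluded. The numbers were checked for pairing through deviations from the genotype means, which correlated across probes at r = 0.791, 0.314, 0.493 and 0.740 for mice of the same number in pairs 1 to 4. The highest correlation with another number was 0.387, 0.691, 0.387 and 0.691. Every pair lay above 0.1, but the 2 channels of 1 array share every spot, so this check could hardly fail. In pair 2 the correlation was higher with another number. The numbers were taken to pair the samples because the members of a pair shared an array. All adjusted p-values are limma's with Benjamini-Hochberg adjustment, two-sided, over all probes tested unless stated, at a threshold of 0.05. The sex difference was fitted as a genotype-by-sex term with 1 residual degree of freedom. An error is the SD over the 4 pairs unless stated.

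The design, the gene lists and the rule for naming genes were fixed before the data were examined. Of 39 lists, drawn from textbook knowledge of pseudouridylation, mitochondria, stress responses and brain cell types and regions, 37 were tested with camera (preset correlation 0.01) and adjusted over the lists. The list of mitochondrially encoded proteins had no tested member under these names, and the list of sex-specific genes served to check the labels. Camera with an estimated correlation and fry, which asks whether a list's genes moved one way on balance, were run beside it. With the preset correlation, a list's genes are set against all other genes. The p-value then measures spread between genes and not spread over the 4 pairs, so a very small one does not show replication over mice. Camera with an estimated correlation has only the fit's residual degrees of freedom, so few lists could pass it. Its p-values do not by themselves show that correlation between genes accounts for the lists passed with the preset value. Members were counted over all probes and adjusted over the list alone. The rule names Pus1, up to 10 genes past the test in each direction (filled to 5 by the smallest p among genes of 1 sign on all arrays), up to 4 members of each list past the test, or its 2 brightest members where none passed, and 2 genes in each direction for the sex difference. The result of 1 gene under this rule is not reported here. That "past the test" for list members means adjusted over the list alone was settled once the data were in hand.

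Alternatives were no background correction, the scanner software's own ratio, median centring, scaling between arrays, no filter and a filter on all 8 samples, no dye term, an intensity trend with a robust prior, separate channels with no replicate block or with the array as a random block, the authors' table, a sex term, 1 probe per gene, a 1.5-fold minimum, and leaving out each pair. With the dye term and a pair left out, the remaining pair of its orientation weighs as much as both pairs of the other orientation together. The spread then comes from that other orientation alone. The counts of list members and the sex differences of lists, without each pair and without the dye term, were added after seeing the data.

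The steps were tested on simulated data for the 33300 probes of the genotype comparison, with noise of the real residual spreads drawn independently for each probe. At a log2 change of 0.5, 0 of 67 changed probes were recovered, at 1 it was 2 of 67 (2.99%) and at 2 it was 32 of 66 (48.5%), with 0 false calls. A list shifted by 0.5 was recovered and 0 other lists were called. The simulated probes were uncorrelated, so this cannot show how often lists of correlated genes are called falsely. Among the 8 lists that passed, the estimated correlation was 0.92 for immediate early genes, 0.77 for interferon response genes and 0.57 for excitatory neuron markers. It was 0.39 for cerebellar, 0.30 for ependymal and 0.11 for hypothalamic and pituitary markers, 0.05 for ATF4 targets and -0.04 for cytosolic synthetases. Where the correlation lies above the preset 0.01, the preset p-value is too small. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.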

Results

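Gene expression in brain was compared between mice homozygous for a mutated Pus1 gene and wild-type mice, 4 of each genotype. Pus1 encodes pseudouridine synthase 1, an enzyme that converts uridine to pseudouridine in cytosolic and mitochondrial tRNAs and in other RNAs. The 8 mice were hybridised in 4 pairs, 1 mutant and 1 wild type per array. Between 56.3% (Cy5, pair 2) and 67.7% (Cy3, pair 1) of probes lay well above background in a channel, and 28314 probes did so in all 8 samples. Median spot brightness was 119.5 to 136 in Cy3 over a background of 47 to 58, and 293 to 318 in Cy5 over a background of 144 to 148. Between 20 and 26 spots per array were saturated in Cy5 and 0 in Cy3. The log2 ratios spread most in pair 2, with an SD of 0.633 and 2891 probes over 2-fold, against 0.279 and 180 in pair 1, 0.395 and 801 in pair 3, and 0.329 and 368 in pair 4. Mutant over wild-type ratios correlated across probes at r = 0.34 between pairs 1 and 3 and 0.26 between pairs 2 and 4, which share a dye orientation. Between orientations r was -0.39 for pairs 1 and 2, -0.10 for 1 and 4, -0.14 for 2 and 3, and 0.07 for 3 and 4. Probes are not independent replicates. Xist was well above background in 4 of 4 females and 0 males, and Ddx3y, Eif2s3y and Uty in 0 females and 4 of 4 males, and Kdm5d in 0 females and 2 males, as the labels give the sexes.

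The first question was whether the targeted transcript was reduced. Pus1, on chromosome 5 and measured by 1 probe (A_55_P2056100), fell by 2.59 ± 0.38 on the log2 scale (SD, n = 4 pairs), 6.03-fold, with adjusted p = 0.0364 in limma. The fall was larger on other scales, -3.82 with the scanner software's ratio and -3.83 in the authors' table. Its log2 mutant over wild-type ratio was -2.07, -2.94, -2.61 and -2.75 in pairs 1 to 4. The normalized log2 intensity was 7.01 ± 0.18 in the mutant, where 3 of 4 samples were well above background, and 9.60 ± 0.42 in wild type, where 4 of 4 were. Whether this probe lies in the altered part of the gene is not given in the sources used here. The direction held in every alternative that measured Pus1, but adjusted p rose to 0.199 with the scanner software's ratio, to 0.0822 in the authors' table, to 0.0556 with no replicate block, and to 0.893 and 1.00 without replicate 1 or 3 (range over the alternatives 0.000399 to 1.00).

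The second question was which other transcripts differed between mutant and wild-type brain. Trib3, a pseudokinase induced by the transcription factor ATF4, rose 4.04-fold (log2 2.01 ± 0.53), with 2.46, 1.67, 2.47 and 1.46 in pairs 1 to 4. Pus1 and a probe without a gene name (A_55_P2097578, log2 -1.91 ± 0.10) were the transcripts that fell. Each of these 3 probes had adjusted p = 0.0364, out of 33300 tested. The next genes upward had the same sign in all 4 pairs but did not pass. They were Chac1, a glutathione-degrading enzyme (log2 1.54 ± 0.08, adjusted p = 0.0902), the collagen receptor Ddr2 (1.31 ± 0.48, adjusted p = 0.157, with 0.66 at another probe), the secreted stress factor Fgf21 (1.42 ± 0.32, adjusted p = 0.181, above background in 4 mutant and 1 wild-type sample, and 3.00 with the scanner software's ratio) and the cerebellar synapse organiser Cbln1 (1.25 ± 0.72, adjusted p = 0.184). Downward, the ATP-gated channel P2rx7 (-1.43 ± 0.35, adjusted p = 0.282) had -0.23 and -0.11 at other probes. The potassium channel Kcnh5 (-0.86 ± 0.38), Tmem132d (-1.53 ± 1.10) and Scube1 (-1.05 ± 0.91) had adjusted p = 0.452. Some of these genes split by dye orientation, with 1.76, 0.92, 1.68 and 0.88 in pairs 1 to 4 for Ddr2. Cbln1 had 0.75, 1.84, 0.52 and 1.91, and Scube1 -0.03, -2.05, -0.60 and -1.54. Without the dye term limma gave adjusted p = 0.0459 for Chac1, 0.244 for Fgf21, 0.260 for P2rx7 and 0.665 for Ddr2. It gave 0.999 for Cbln1, Kcnh5, Tmem132d and Scube1.

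At an unadjusted p under 0.05 there were 2014 probes, 1011 higher and 1003 lower, where 1665 would be expected by chance. The same sign in all 4 pairs was seen at 3928 probes, 11.8% against 12.5% by chance. The count of 3 probes became 0 with the scanner software's ratio, in the authors' table and with a sex term, 1 with no replicate block, 11 with an intensity trend and 25 with the array as a random block. It was 0 without replicate 1, 13 without replicate 2, 0 without replicate 3 and 934 without replicate 4, and both Trib3 and A_55_P2097578 had adjusted p = 0.893 and 1.00 without replicates 1 and 3 and 0.206 with the scanner software's ratio, while without the dye term Trib3 had 0.223 and A_55_P2097578 0.0335 (range over the alternatives 0.0119 to 1.00).

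The gene lists asked which pathways and cell types moved together. The smallest p belonged to the list of ATF4 and integrated stress response targets, genes for amino acid synthesis and transport, one-carbon metabolism and stress signalling. Of its 27 measured members 25 were higher in the mutant and 20 were higher in all 4 pairs, with a median log2 of 0.57. The list median was nearly the same in every pair, at 0.58, 0.58, 0.65 and 0.53. Adjusted over the list alone 19 members rose and none fell, against 1 over all probes. Besides Trib3, Chac1 and Fgf21 they included the secreted factor Gdf15 (1.30 ± 0.32, above background in 4 mutant and 3 wild-type samples, and 2.63 with the scanner software's ratio), the enzymes of mitochondrial folate metabolism Mthfd2 (1.18 ± 0.53), Shmt2 (0.81 ± 0.18) and Aldh1l2 (0.99 ± 0.15), asparagine synthetase Asns (1.01 ± 0.27), and the transcription factors Atf4 (0.72 ± 0.68), Atf5 (0.73 ± 0.19) and Ddit3 (0.45 ± 0.05). The cystine transporter Slc7a11 (-0.01 ± 0.49) and the amino acid transporter Slc7a5 (-0.13 ± 0.46, with 0.77 ± 0.15 at another probe) did not pass. Apart from Trib3, Chac1, Fgf21 and Gdf15, the members named here were chosen after their values were seen. Camera gave adjusted p = 2.16e-27, with adjusted p = 0.399 with an estimated correlation, and fry gave 0.0426. The first of these reflects spread between genes, not over the 4 pairs. The estimated correlation of this list was 0.05, above the preset 0.01.

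**Figure D1:**
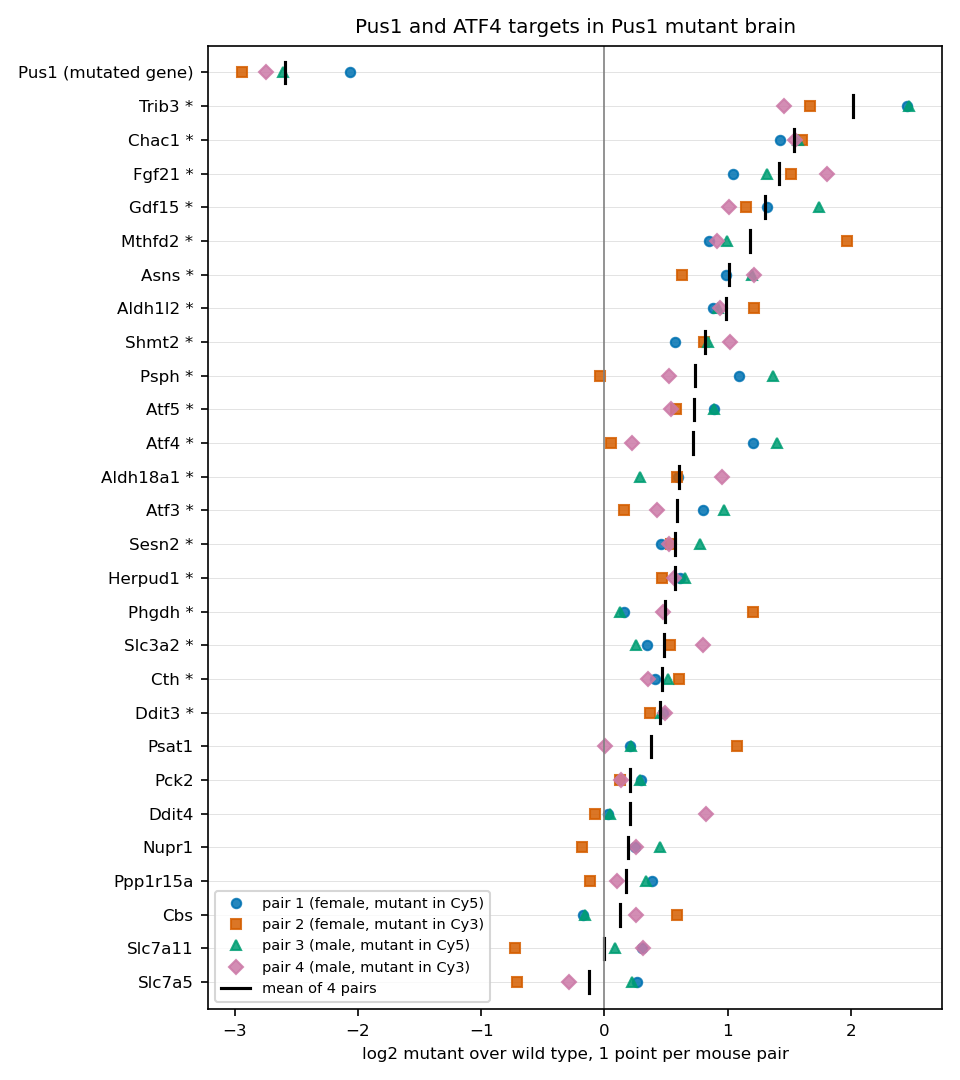
Log2 mutant over wild-type ratios of Pus1 and of the 27 measured ATF4 targets, 1 point per mouse pair, with the mean of the 4 pairs as a black bar. An asterisk marks the 19 members that rose when adjusted over the list alone, and the points of Pus1 lie between -2.94 and -2.07.

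The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and several of which ATF4 is also known to induce, were higher in the mutant for 16 of 20 members, 11 of them in all 4 pairs. The list median was 0.30, with 0.27, 0.40, 0.16 and 0.38 in pairs 1 to 4. Adjusted over the list alone 9 rose, against 0 over all probes, led by the synthetases for cysteine (Cars, 0.75 ± 0.20), asparagine (Nars, 0.72 ± 0.37), glycine (Gars, 0.59 ± 0.06) and alanine (Aars, 0.53 ± 0.17). Camera gave adjusted p = 1.04e-08, with adjusted p = 0.399 with an estimated correlation, and fry gave 0.0426. The estimated correlation of this list was -0.04, below the preset 0.01, so the higher p does not come from correlation between its genes. The 9 members became 0 without replicate 1 and 0 without replicate 3. The mitochondrial synthetases did not pass, with a median of -0.05 and adjusted p = 0.415 over 15 members, and the difference between these lists was not tested. Their brightest members were Tars2 (-0.09 ± 0.16, with 0.06 at another probe) and Fars2 (-0.00104 ± 0.05).

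Cerebellar markers were higher in the mutant at all 13 measured members, 10 of them in all 4 pairs. The median was 1.05, but pairs differed, at 0.63, 0.31, 0.76 and 1.91. Adjusted over the list alone 8 rose, among them Cbln1, the transcription factors Zic1 (1.23 ± 0.67) and Zic2 (0.76 ± 0.45) and the Purkinje cell glutamate transporter Slc1a6 (0.64 ± 0.49), against 0 over all probes. Camera gave adjusted p = 1.86e-12, with adjusted p = 0.920 with an estimated correlation, and fry gave 0.594. The estimated correlation of this list was 0.39, above the preset 0.01. The 8 members became 1 without replicate 1 and 3 without replicate 3, and the median was 0.61 without replicate 4 (adjusted p = 4.72e-06). In pair 4 striatal markers had a median of -1.22 beside the cerebellar 1.91.

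Immediate early genes, which report recent neuronal activity, had a median of -0.53 over 21 members, and excitatory neuron markers one of -0.56 over 12. Both rested on pair 2, where the medians were -2.26 and -2.21, against 0.26, 0.31 and -0.27 for the immediate early genes and 0.25, -0.18 and -0.15 for the neuron markers in pairs 1, 3 and 4. Npas4 (-0.88 ± 1.35) was the 1 immediate early gene past the test adjusted over the list alone, although its ratios were 0.05, -2.21, 0.48 and -1.86 in pairs 1 to 4. No excitatory marker passed, the brightest being Nrgn (-0.57 ± 0.95) and Neurod2 (-0.36 ± 1.14). Camera gave adjusted p = 2.06e-07 and 0.000566, each with adjusted p = 0.920 with an estimated correlation. Without replicate 2 the medians were -0.04 (adjusted p = 0.520) and -0.15 (adjusted p = 0.616). Without replicate 4 they were -0.97 (6.24e-19) and -1.07 (4.86e-09), in a fit where pair 2 weighs as much as pairs 1 and 3 together.

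Interferon response genes had a median of 0.18 over 19 members (camera adjusted p = 0.00743, and adjusted p = 0.959 with an estimated correlation). Their median was 0.73 in pair 2 and -0.03, -0.02 and 0.04 in pairs 1, 3 and 4, and without replicate 2 it was -0.02 (adjusted p = 0.803) and without replicate 4 it was 0.34 (4.74e-06). No member passed, the brightest being Lgals3bp (0.17 ± 0.57) and Irf9 (0.15 ± 0.18). Ependymal cell markers had a median of -0.24 over 10 members (camera adjusted p = 0.0223, and adjusted p = 0.920 with an estimated correlation), with -0.59, 0.70, -0.67 and -0.16 in pairs 1 to 4. Adjusted over the list alone Enkur (-0.49 ± 0.19) and Tmem212 (-0.43 ± 0.60) passed, the latter with -1.01, -0.04, -0.88 and 0.19 in pairs 1 to 4. With the scanner software's ratio Enkur had -0.86 and Tmem212 -0.78. The call was lost without replicate 1 (adjusted p = 0.0751), without replicate 4 (0.822), without the dye term (0.0501) and in separate channels with no replicate block (0.176) or with the array as a random block (0.0723). The median was -0.39 without replicate 2 (3.21e-07), -0.01 without replicate 4 and -0.38 in the authors' table (0.00165). Hypothalamic and pituitary markers had a median of 0.35 over 14 members (camera adjusted p = 0.000360, and adjusted p = 0.920 with an estimated correlation), with -0.22, 0.68, 0.10 and 0.55 in pairs 1 to 4. The hormone genes Trh (1.33 ± 1.87), Oxt (1.45 ± 0.87), Ghrh (0.44 ± 0.65) and Avp (1.40 ± 1.09) passed when adjusted over the list alone, and of these Oxt alone had the same sign in all pairs. In pairs 1 to 4 the ratios were -0.44, 3.69, 0.16 and 1.92 for Trh, -0.10, 1.12, -0.12 and 0.89 for Ghrh, and 1.48, -0.15, 1.99 and 2.30 for Avp, and the dye term takes up a shift shared by pairs of 1 orientation. Avp was 0.79 without replicate 4. Without replicate 3 that list had a median of 0.24 and adjusted p = 0.102, and without replicate 1 it had 0.68 and 2.79e-07. Of 37 lists 8 passed with the preset correlation, 5 higher and 3 lower, 0 passed in camera with an estimated correlation (2 at an unadjusted p under 0.05) and 2 in fry.

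**Figure D2:**
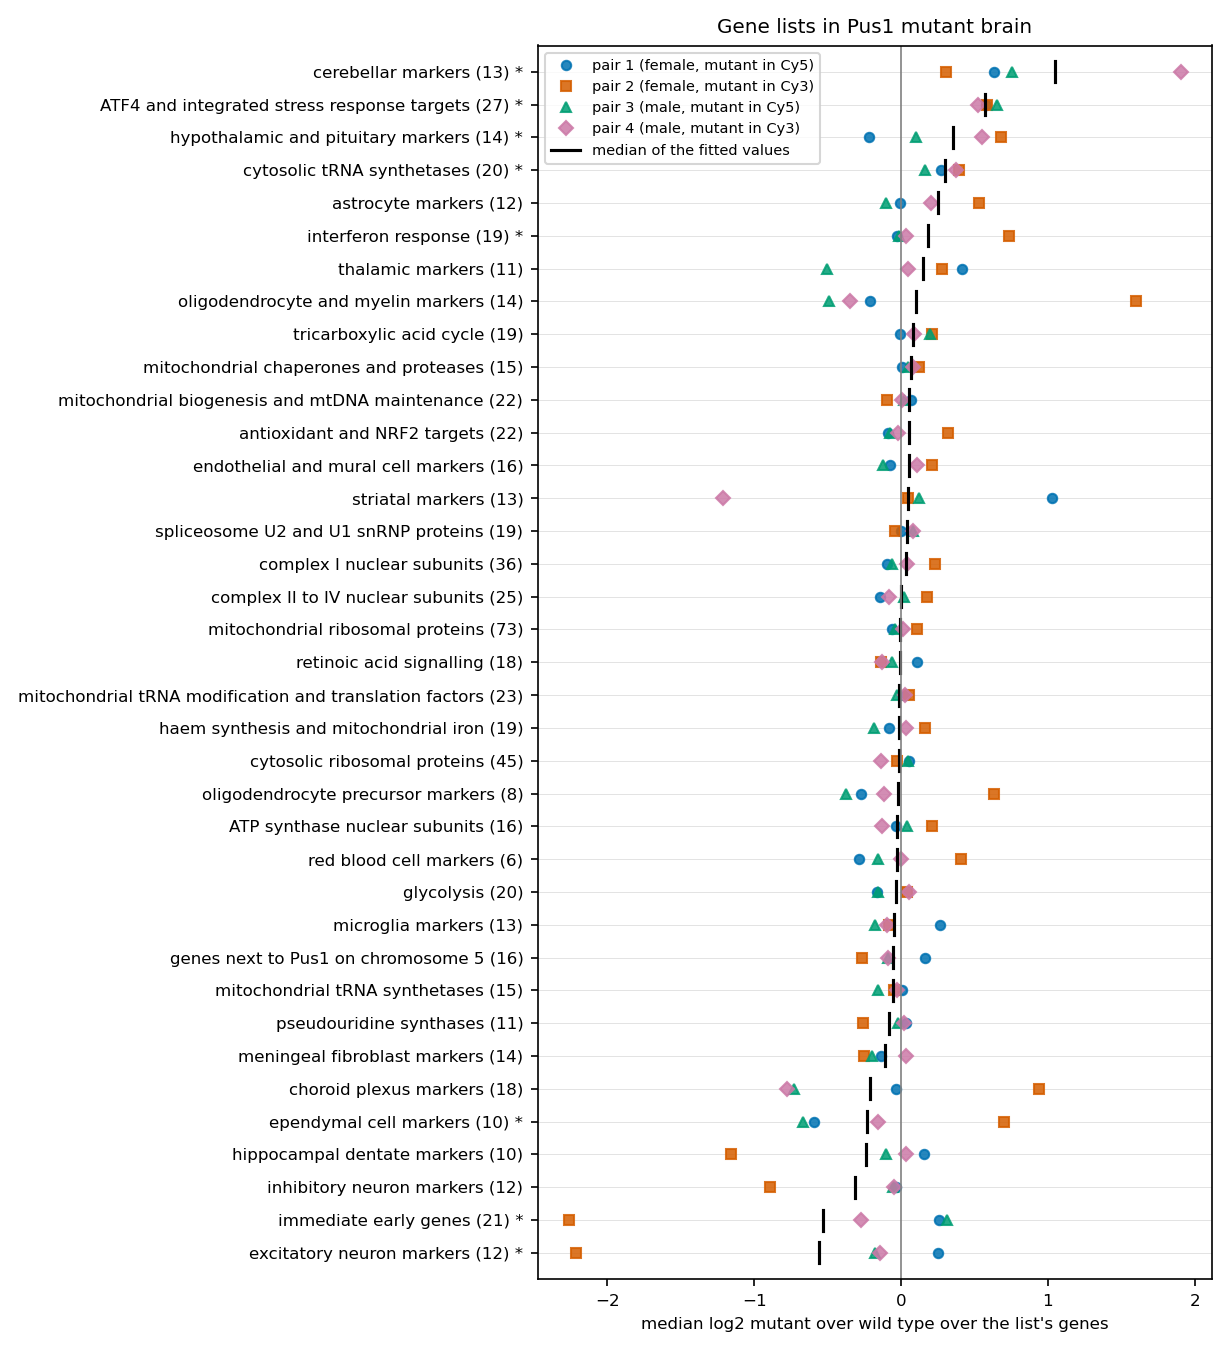
Median log2 mutant over wild-type ratio of each gene list in each of the 4 mouse pairs, with the number of measured members in brackets and the median of the fitted values as a black bar. An asterisk marks the 8 lists past the camera test, and pair 2 lies at -2.26 for immediate early genes and at 1.60 for myelin markers.

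The mitochondrial and translation lists did not pass, and no member of them passed, but 4 of the lists passed under another setting, as given beside them. Nuclear subunits of complex I had a median of 0.03 over 36 members (adjusted p = 0.686), with Ndufa13 at 0.02 ± 0.11 and Ndufa5 at 0.06 ± 0.06. Those of complexes II to IV had -0.00202 over 25 (0.611), with Cox6a1 at -0.16 ± 0.54 and Cox8a at -0.44 ± 0.39. With median centring they had -0.11 (0.0131, with 0.0131 to 0.982 over the alternatives). The ATP synthase list had a median of -0.03 and a mean of 0.01 over 16 (0.992), with Atp5b at -0.04 ± 0.40 and Atpif1 at -0.11 ± 0.18. Mitochondrial ribosomal proteins had -0.01 over 73 (0.783), with Mrpl20 at -0.04 ± 0.19 and Mrps33 at 0.06 ± 0.28. Mitochondrial tRNA modification and translation factors had a median of -0.01 and a mean of 0.00 over 23 (0.966), with Mtif2 at 0.26 ± 0.51 and Lrpprc at -0.01 ± 0.20. Mitochondrial biogenesis genes had 0.05 over 22 (0.510), with Esrra at -0.01 ± 0.33 and Dnm1l at 0.08 ± 0.24. Mitochondrial chaperones and proteases, markers of a mitochondrial unfolded protein response, had 0.07 over 15 (0.302), with Hspd1 at 0.13 ± 0.15 and Lonp1 at 0.12 ± 0.13. The tricarboxylic acid cycle had 0.08 over 19 (0.0784), with Mdh2 at -0.01 ± 0.20 and Mdh1 at -0.00471 ± 0.30. It passed with no filter and in both separate-channel fits, with 0.0348 to 0.641 over the alternatives. Glycolysis had -0.04 over 20 (0.356), with Aldoc at 0.42 ± 0.59 and Gapdh at -0.12 ± 0.40. With median centring its median was -0.17 (0.0340, with 0.0340 to 0.849 over the alternatives). Haem synthesis and mitochondrial iron genes had -0.02 over 19 (0.698), with Fth1 at -0.08 ± 0.59 and Ftl1 at -0.12 ± 0.21. Cytosolic ribosomal proteins had -0.02 over 45 (0.607), with Rps14 at -0.24 ± 0.75 and Rpl41 at -0.13 ± 0.10. With median centring their median was -0.13 (0.000289, with 0.000289 to 0.837 over the alternatives).

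The other pseudouridine synthases did not pass either, with a median of -0.08 over 11 members (adjusted p = 0.773), Trub2 at 0.07 ± 0.34 (-0.11 at another probe) and Rpusd3 at -0.09 ± 0.24. The 16 measured members of the list fixed as neighbours of Pus1 on chromosome 5 had a median of -0.05 (0.266), with Ulk1 at 0.02 ± 0.21 and Pgam5 at 0.00 ± 0.41. That list was not complete, as Mn1, 5 tested genes from Pus1 in gene order, was not in it. Antioxidant genes had 0.05 over 22 (0.266), with Sod1 at -0.06 ± 0.23 and Gpx4 at 0.06 ± 0.38, and passed without replicate 4 (0.13, adjusted p = 0.0309, with 0.0309 to 0.845 over the alternatives). Retinoic acid signalling had -0.01 over 18 (0.698), with Aldh1a1 at 0.44 ± 1.25 and Rxrb at -0.08 ± 0.21. Spliceosomal U1 and U2 proteins had 0.04 over 19 (0.698), with Snrpd2 at -0.04 ± 0.12 and Snrnp70 at -0.17 ± 0.48.

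The remaining lists of cell type and region markers did not pass in the main fit, and their medians differed between pairs. Oligodendrocyte and myelin markers had a median of 0.10 over 14 members (adjusted p = 0.792), with 1.60 in pair 2 and -0.21 to -0.49 in the others, and Ermn at -0.26 ± 0.35 (0.25 at another probe). They passed downward without replicate 2 (-0.41, 1.57e-09) and upward without replicate 4 (0.61, 5.07e-07), with adjusted p up to 0.866 over the alternatives. Their precursor cells had -0.02 over 8 (0.510), with Olig1 at 0.03 ± 0.76 and Gpr17 at -0.12 ± 0.22, and passed downward without replicate 2 (-0.20, 0.0165, with 0.0165 to 0.877 over the alternatives). Astrocyte markers had 0.25 over 12 (0.0673), with S100b at 0.32 ± 0.94 and Acsbg1 at 0.26 ± 0.56. They passed upward in 5 settings, which were no filter, both separate-channel fits, without replicate 3 (0.24, 0.0385) and without replicate 4 (0.30, 0.0188), with 0.0124 to 0.409 over the alternatives. Inhibitory neuron markers had -0.32 over 12 (0.158), with Cck at -1.27 ± 2.07 and Slc32a1 at 0.37 ± 0.55, and passed without replicate 4 (-0.58, 0.00203, with 0.00203 to 0.520 over the alternatives). Microglia had -0.05 over 13 (0.455), with Itgam at 0.10 ± 0.34 and Csf1r at -0.04 ± 0.21 (0.03 and 0.07 at other probes). Endothelial and mural cells had 0.05 over 16 (0.773), with Ly6c1 at 0.12 ± 0.38 and Flt1 at 0.14 ± 0.33.

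Choroid plexus markers had a median of -0.21 over 18 members (adjusted p = 0.302), from 0.94 in pair 2 to -0.77 in pair 4, with Enpp2 at -0.25 ± 1.13 and Ttr at -0.31 ± 2.86. They passed downward without replicate 1 (-0.32, 0.0386) and replicate 2 (-0.57, 8.78e-10) and upward without replicate 4 (0.26, 0.00578), with adjusted p up to 0.911 over the alternatives. Meningeal fibroblasts had -0.11 over 14 (0.0673), with Mgp at -0.31 ± 0.16 and Dcn at 0.45 ± 0.70. They passed downward in 5 settings, which were no filter, no dye term, the intensity trend, the authors' table (-0.18, 0.0334) and without replicate 4 (-0.24, 0.0191), with 0.0191 to 0.692 over the alternatives. Red blood cell genes had a median of -0.03 and a mean of 0.02 over 6 (0.966), with Hba-a1 at -0.16 ± 0.45 and Hbb-b2 at -0.05 ± 0.32. Striatal markers had 0.05 over 13 (0.773), from 1.03 in pair 1 to -1.22 in pair 4, with Penk at 0.21 ± 1.26 and Ppp1r1b at -0.10 ± 0.90. They passed downward without replicate 2 (-0.25, 0.0213) and upward without replicate 3 (0.23, 0.00887) and replicate 4 (0.23, 0.0126), with adjusted p up to 0.992 over the alternatives. Thalamic markers had 0.15 over 11 (0.356), and Calb2 (1.60 ± 0.83) rose when adjusted over the list alone. They passed without replicate 3 (0.37, 2.13e-05, with 2.13e-05 to 0.671 over the alternatives). Hippocampal markers had -0.24 over 10 (0.223), with Wfs1 at -0.04 ± 0.50 and Hs3st4 at -0.53 ± 0.75, and passed without replicate 4 (-0.57, 6.01e-05, with 6.01e-05 to 0.322 over the alternatives). The median of all tested ratios was 0.00 after loess, which centres each array.

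The last question was whether the effect of the mutation differed by sex, with 2 pairs of each. The fall of Pus1 was -2.50 in females and -2.68 in males, a difference of 0.18 ± 0.30 (SE, adjusted p = 0.993), and the median of the ATF4 targets was 0.54 in females and 0.62 in males. No probe passed in limma, with 925 at an unadjusted p under 0.05. The smallest p-values, none past the threshold at adjusted p = 0.993, belonged to Gm5741 (female minus male 2.33 ± 0.27, SE, from 0.07 and -2.26), the choroid plexus channel subunit Kcne2 (2.62 ± 0.36, from 0.93 and -1.69), the hormone gene Oxt (-1.50 ± 0.26, from 0.70 and 2.20) and Gm14625 (-1.47 ± 0.33, from -0.06 and 1.41). The count of 0 became 9 with an intensity trend. Fits that left out a pair had no dye term, and they gave 1381 without replicate 1 and 0 without replicates 2, 3 and 4, where all 4 pairs without the dye term gave 0 (269 at an unadjusted p under 0.05).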

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

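The sex comparison of whole lists, with and without each pair, and all tests of explanations in this part were chosen after the result was seen.

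Among 128 sets of 4 pair values checked, 7 had 1 pair far from the rest, where chance gives about 1 set in 20, and all 7 lay in pair 2. Neurod2, a transcription factor of excitatory neurons, was at -2.06 in pair 2 against 0.08 to 0.28 in the others. Hs3st4 was at -1.64 against -0.29 to -0.01, and Pgam5 at -0.61 against 0.12 to 0.25. The list median in pair 2 was -0.89 for inhibitory neuron markers against -0.05 to -0.04, 1.60 for myelin markers against -0.49 to -0.21, 0.73 for interferon response genes against -0.03 to 0.04, and 0.32 for antioxidant genes against -0.09 to -0.02.

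With the preset correlation of camera, 11 lists differed between the female and the male pairs, and none did with an estimated correlation (smallest adjusted p = 0.876). The female minus male median was 1.19 for striatal, 1.13 for choroid plexus, 1.09 for myelin and 1.06 for thalamic markers, and 0.45 for oligodendrocyte precursor, 0.41 for ependymal and 0.25 for interferon response genes. It was -1.09 for excitatory neuron markers, -1.01 for immediate early genes, -0.82 for hippocampal and -0.78 for cerebellar markers. Most of these differences rested on 1 pair. In fits without the dye term that left out each pair in turn, 2 of the 11 lists passed every time in the same direction, choroid plexus (lowest 0.70, without pair 2) and thalamic markers (0.56 without pair 2 and 0.48 without pair 3). Without pair 2, excitatory neuron markers turned to 0.49 (adjusted p = 4.22e-05), immediate early genes to 0.27 (6.11e-05), ependymal markers to -0.15 (0.0612) and interferon response genes to -0.0280 (0.351). Myelin (0.22, 0.0900), hippocampal (-0.0247, 0.837) and oligodendrocyte precursor markers (0.0296, 0.904) lost their call without that pair. Without pair 4 the call was lost for cerebellar (-0.22, 0.425), striatal (0.38, 0.0854), excitatory neuron (-1.01, 0.215), precursor (0.83, 0.0723) and interferon response genes (0.25, 0.0884). It was lost without pair 1 for striatal (0.39, 0.0866) and cerebellar markers (-0.79, 0.0646), and without pair 3 for ependymal (0.18, 0.556) and precursor markers (0.18, 0.337). Without pair 1, where pair 2 was the 1 female pair left, the values were -2.41 for excitatory neuron, -2.20 for immediate early, -1.44 for hippocampal, 2.00 for myelin, 1.01 for ependymal, 0.93 for precursor and 0.64 for interferon response genes. Without pair 3 they were -1.54 for cerebellar and 1.81 for striatal markers, and without pair 4 ependymal markers were at 0.63 and hippocampal markers at -0.55. With all 4 pairs and no dye term, excitatory neuron (0.0634), ependymal and precursor markers (0.0781 each) did not pass.

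The shifts of brain region and cell type markers form 1 pattern, weighed against the level at which each brain was sectioned and against a genotype effect. A genotype effect on excitatory neuron markers in every pair was argued against by their highest pair median of 0.254, against -2.21 in pair 2. Medians of 5 region lists lay up to 3.12 apart within a pair (1.25, 1.84, 1.26 and 3.12 in pairs 1 to 4). Different section levels between the mice of a pair could give such gaps. A genotype effect that differs by region could give them too, so the gaps cannot tell these apart, and they do not bear on lists that are not of regions. For the cerebellar markers both stay open, because their lowest pair median of 0.307 was above 0, as a genotype effect would also give (1 of the cerebellar markers, Calb1, is also in the hippocampal list). Sex stays open as well, untested beyond the list comparison.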

How the results depend on the processing

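The counts of list members without each pair and without the dye term were chosen after seeing the data. The count of 3 probes was within 1.5 times in 8 settings, but without the dye term only 2 of the 3 were the same. It was 0 with the scanner software's ratio, in the authors' table and with a sex term, 11 with an intensity trend, 1 in separate channels with no replicate block and 25 with the array as a random block, and it ranged from 0 to 934 when 1 replicate was left out. The high count came without replicate 4. Pus1 kept its direction in all 14 settings that measured it and its call in 9, losing it with the scanner software's ratio (-3.82, adjusted p = 0.199), in the authors' table (-3.83, 0.0822), with no replicate block (-2.59, 0.0556) and without replicates 1 and 3 (-2.73 to -2.46). It was not tested where all 8 samples had to be above background. Of the lists, 8 passed in the main analysis, 0 with an estimated correlation, 2 in fry and 8 to 15 when 1 replicate was left out, and in 14 settings the count stayed within 1.5 times. Another 14 lists passed under some alternative, 10 of them when a replicate was left out. The ATF4, synthetase and cerebellar lists passed in all 15 alternatives of the fit, with adjusted p up to 2.60e-12, 8.74e-05 and 0.00960. Of 120 list medians 111 kept their call, 8 lost it, and that of interferon genes (main 0.18) turned to -0.0202 without replicate 2, within -0.0202 to 0.343 over the replicates left out. Members that rose, adjusted over the list alone, were 19 in the ATF4 list (13 to 20 without a replicate, 18 without the dye term), 9 synthetases (0 to 9, and 6) and 8 cerebellar markers (1 to 12, and 8). Trib3 and the unnamed probe kept their call in 9 of 16 settings and lost it in 7, and the other 24 named genes, which had no call, gained one in 17 of 190. The sex count of 0 became 9 with an intensity trend and 0 to 1381 without a replicate, in fits without the dye term, where all 4 pairs gave 0. The pairing by array is part of the main fit. In separate channels the call of ependymal markers ended with no replicate block (camera adjusted p = 0.176) and also with the array as a random block (0.0723). Its loss can therefore not be put down to ignoring the pairing. Dim genes such as Fgf21 are limited by signal over background. The probe counts without a replicate depend on the design, since the spread then comes only from the orientation with both pairs left. That is pairs 1 and 3 without replicate 2 or 4, and pairs 2 and 4 without replicate 1 or 3. The log2 ratios of pair 2 spread most (SD 0.633). A sex fit without a replicate leaves 1 unreplicated pair in a sex. The cause of the other changes was not tested.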

Other observations

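All tests of explanations in this part were chosen after the result they address was seen. That of the endoplasmic reticulum genes was set after the ATF4 result but before the values of those genes were seen. The genes of the next paragraph were chosen after their values were seen.

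Beyond the fixed lists, the cationic amino acid transporters Slc7a3 and Slc7a1 had log2 ratios of 1.55 ± 0.52 and 0.69 ± 0.18, above 0 in all 4 pairs, and did not pass over all probes (adjusted p = 0.452 for both). The peptide hormone gene Adm2 had 1.40 ± 0.23 (adjusted p = 0.204) and was above background in 4 mutant and 2 wild-type samples. Among hormone genes of the lateral hypothalamus, Pmch, which encodes melanin-concentrating hormone, had 4.88, 0.95, -1.16 and 4.96 in pairs 1 to 4, and Hcrt, which encodes orexin, 2.56, 0.66, -0.01 and 2.74.

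The rise of the ATF4 targets was weighed against dye, tissue and another stress pathway. Dye bias would turn the sign between orientations, but the lowest pair median was 0.526, and a larger share of cerebellum would raise the list most in pair 4, but pair 4 less pair 2 was -0.0558. A broad unfolded protein response in the endoplasmic reticulum would raise its chaperones and genes of protein transport and degradation there. The median of 20 such genes, Hspa5 and Xbp1 among them, was 0.0349, with 0 past the test when adjusted over the list alone. These genes do not measure a branch of that response that acts through ATF4, so such a branch stays open. The real split of the mice gave a median of 0.57, with 0.435 as the highest other of the 8 splits that part all 4 pairs, which are too few for a share under 0.05, and 0.492 as the highest other of all 35 splits, most of which set both mice of a pair on 1 side. That loss of Pus1 may raise ATF4 signalling stays a hypothesis, and no value here separates it from an effect of genes linked to Pus1.

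Genes of chromosome 5 were frequent among those at an unadjusted p under 0.01 with 1 sign in all pairs, 18 of 935 (1.93%) against 168 of 14347 elsewhere (1.17%), which chance placement could give (Fisher's exact test, two-sided p = 0.0619). Within the chromosome 16 of the 400 genes nearest Pus1 in gene order were such genes (4.00%), against 2 of 535 farther away (0.374%), with a one-sided Fisher's exact p = 5.96e-05. These reached out to 197 tested genes from Pus1 in a window of 200 on each side, and no other window was tried. The nearest were Mn1 at 5 and Crlf2 at -17, and the fixed list of neighbours did not pass (camera adjusted p = 0.266). Strain variants under the probes would lower the signal, and 9 of the 18 were higher, Hsd17b11 (0.85 ± 0.29) among them, which argues against them for that part. For the lower genes they cannot be told apart from a real fall, because the 3 with another probe differed, from P2rx7 at -0.23 and -0.11 to Diablo at -0.36 against -0.55. A candidate explanation is DNA linked to Pus1 that stayed with it through 5 backcrosses, which was not tested by genotype.

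The 8 sign patterns of the 4 pairs are too few for a share under 0.05. As many probes as the real 3 came from 2 patterns, with 319 as the highest other, when pair 4 was turned, and as many lists as the real 8 came from 6, with 15 as the highest other. The ATF4 list still passed camera with any 1 pair turned, at adjusted p from 5.59e-09 to 0.00461. With 2 pairs turned it did not pass (0.480 to 0.950). In separate channels 2 of the 35 splits of the mice gave as many probes as the real 1, so chance was not excluded. The highest other, 10938 probes, set both mice of pairs 1 and 3 against both mice of pairs 2 and 4. Each side held both dyes in equal number and the fit had a dye term. A dye bias common to the arrays can therefore not give this difference between samples or arrays, whose cause was not tested. The splits that part all 4 pairs, the real one aside, gave 0.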
